A study of Mus musculus with 7 samples.

How the data were processed

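ATAC-seq libraries of sorted adipose tissue macrophages from 3 diet groups (HFD n = 3, HFD-RD n = 2, RD-RD n = 2) were compared through the 7 processed tables of the series. The titles and the diet labels give each library its group. The source names of all 7 libraries name another diet than these do, in an order that looks shifted against the titles. Titles and diet labels were followed. The values group the libraries as the titles do, but in regions selected for differing between these groups, so this does not decide between the labels. The submitters' processing notes name Picard, deepTools, MACS2 2.0.10 and DESeq2 and the build GRCm38, without their roles; the aligner and the filters are not given in the sources used here.

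Each deposited table is a part of a Venn diagram and lists regions with their nearest gene. The deposited signal (coverage of a region by reads, given by the authors as normalized counts) is the read count divided by 1 size factor per library. This was checked on the values: within a tolerance of 1e-06, 100% of each library's values were whole multiples of a single step, and the mean over the 7 libraries equalled the authors' base mean. The recovered steps gave size factors of 0.548 and 1.08 for HFD-RD, 0.803 and 0.694 for RD-RD, and 2.21, 1.22 and 1.16 for HFD. The tables also give the authors' log2 fold change with its standard error, a score that is the authors' Wald statistic, and the authors' p-value and adjusted p-value, each for 1 comparison per table that the column names do not state. The comparison of each table was read from the values, as the group means whose log2 ratio matches the deposited fold change, and the membership of each table in the other comparisons from the share of its regions (at least 85%) that limma called with an absolute log2 change over 0.9. A table gives a fold change for 1 comparison only, so the direction of its regions in the other comparisons is limma's. All deposited regions had an adjusted p of 0.05 or less and an absolute log2 fold change of 1 or more by the authors. Their adjusted p-values imply 74287 regions tested per comparison. Regions outside the deposited tables were not analysed here. Coordinates count from 1, with both ends included.

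The main test was limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with the 3 groups in 1 fit, moderated by the empirical Bayes method without its robust option, and Benjamini–Hochberg adjustment over the 5898 regions of each comparison at 0.05. The authors' DESeq2 run was not repeated. A minimum mean of 10 normalized counts removed 0 regions. Residual degrees of freedom were 4, with a prior of 7.2. Errors of log2 changes are limma's SE, and those of counts the SD between libraries. Depth within the deposited regions ran from 889422 to 2807495 reads and the median region held 71 to 270 reads per library. The limits set by the number of libraries, the depth and the scaling were not compared. On data simulated at these depths with a dispersion of 0.02, limma found 100% of changes of 2 on the log2 scale, 82% of decreases and 80% of increases of 1, and called 21 of 5698 unchanged regions.

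Gene lists and markers were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. There were 9 pathway lists (inflammatory cytokines, chemokines and NF-kB; Toll-like receptor signalling; angiogenesis; lipid-associated macrophages; resident macrophages; core macrophage identity; interferon and antigen presentation; AP-1 and other signal-dependent factors; glycolysis and oxidation) and 10 marker lists of other cell types. The share of a list's regions called higher or lower was compared with that of all other regions with a symbol by Fisher's exact test, two-sided, adjusted over 114 tests. In trials with random lists of 19 genes this test gave p under 0.05 for 13.5% of lists, since regions of 1 gene move together, and for 2.5% with 1 region per gene, so the gene-level p stands beside each list that passed. Adjusted over the list alone, 46 of 46 lipid-associated regions were higher and 18 of 24 resident regions lower in HFD-RD against RD-RD, and 45 and 15 in HFD against RD-RD. In HFD-RD against HFD, adjusted over the list alone, 11 resident regions were lower and 10 of the 17 AP-1 regions higher, and 0 lipid-associated regions were higher. Every other count of a list moved by at most 1 region. The authors' selection used these same libraries, so these counts are not independent evidence.

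The rule named, per comparison, the 5 largest increases and 5 largest decreases past the threshold, 1 region per gene, and the 2 genes with the largest change in each pathway list and in the markers as 1 group, at most 30 genes, and genes of a list among the regions of all 3 comparisons. Other members of a list are given as examples. Place relative to the gene is the deposited annotation. Of 3815 assigned genes 3812 matched the RefSeq gene table by identifier and 3782 had the same symbol there. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

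Alternatives fixed beforehand were an adjusted p under 0.01, a log2 change of at least 1, 1 region per gene, pseudocounts of 0.5 and 4, no filter, leaving out each library, a block for the replicate number, only the 2 groups compared, promoters within 1 or 5 kb, list regions within 10 or 100 kb, genes as units, autosomes only and a 50% reciprocal overlap. Chosen after seeing the data were limma's voom on the recovered reads, equal totals per library with and without the region that holds the most reads, a minimum mean of 50, the nearest protein-coding gene body, all markers as 1 list, and lists counting only log2 changes of at least 1. Motifs were not searched, since no genome sequence was used here. Count-based tests were planned only for tables of raw counts and were not run; voom stood in for them on the recovered reads.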

Results

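Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, on nuclei of adipose tissue macrophages sorted by FACS from adult male C57Bl/6J mice. Mice of the HFD group (n = 3 libraries) ate a diet with 60% lipid for 11 weeks. Mice of the HFD-RD group (n = 2) ate that diet for 11 weeks and then a regular diet with 10% lipid for 9 weeks, which led to weight loss. Mice of the RD-RD group (n = 2) ate the regular diet for 20 weeks. The series frames the question as whether macrophages of formerly obese mice keep a chromatin state tied to inflammation and to blood vessel growth.

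The deposited tables hold 5898 regions, each selected by the authors for a difference in at least 1 of the 3 comparisons out of 74287 regions they tested. Reads recovered within these regions numbered 889422 and 1479141 for the HFD-RD libraries, 1034618 and 916247 for RD-RD, and 2807495, 1523146 and 1566575 for HFD. Libraries of the same group correlated across regions with Pearson's r between 0.941 and 0.972 on the log2 scale, where regions are not independent replicates. Libraries of RD-RD and HFD-RD correlated at 0.401 to 0.53, so the values follow the grouping by title, which the source names of the libraries contradict. The regions were selected for differing between the groups of the titles, which favours this grouping. It therefore does not decide between titles and source names, nor which diet a group ate. The first principal component held 77.5% of the variance and separated RD-RD from both other groups. The second held 12.3% and separated HFD-RD from HFD.

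The comparison of HFD-RD with RD-RD asks what differs after weight loss from mice that were never obese. Regions near genes of lipid-associated macrophages, the cells that take up and break down lipid in obese fat, were more open in HFD-RD. The region inside Lipa, which encodes lysosomal acid lipase, rose from 35.6 ± 9.58 normalized counts in RD-RD (SD, n = 2) to 150 ± 32.2 in HFD-RD (SD, n = 2), a log2 change of 2.06 ± 0.256 (SE). The region inside Cd9, a tetraspanin used as a marker of these macrophages, rose by 2 ± 0.229 (SE) on the log2 scale, from 16.2 ± 3.55 to 67.5 ± 7.73 normalized counts (SD, n = 2 each). Of 24 regions near genes of resident adipose macrophages, 18 were less open. The region over the start of Cd209f, a C-type lectin gene, had a log2 change of -2.89 ± 0.267 (SE), with 214 ± 0.223 normalized counts in RD-RD and 29.3 ± 12.7 in HFD-RD (SD, n = 2 each), and that over the start of Timd4, a phosphatidylserine receptor gene of long-lived macrophages, one of -2.43 ± 0.343 (SE). Of all 314 deposited regions over gene starts, 283 (90.1%) fell in this comparison, so a fall there is not particular to resident macrophage genes.

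In this comparison limma called 3822 of the 5898 regions higher and 1909 lower in HFD-RD, and 167 did not pass (Benjamini–Hochberg over the 5898 regions). The median log2 change was 1.17 among the higher and -1.25 among the lower regions, with a median SE of 0.232. The deposited tables read as holding this comparison have 4989 regions, assigned to 3344 genes, of which limma's log2 change was above 0 in 3202 and below 0 in 1787. Since each region was deposited because it differed somewhere, these counts describe the deposited regions and not the genome, and the limma tests are not independent of the authors' selection.

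The lipid-associated list had regions at 19 of its 32 genes, and all 46 of them rose in HFD-RD, against 64.6% of the other regions (Fisher's exact test, two-sided, adjusted p = 2.53e-07 over 114 list tests). With 1 unit per gene, 19 of 19 genes were higher (adjusted p = 0.00916). The members included Spp1, which encodes osteopontin, with 4 regions at log2 changes of 1.07 to 1.89, Gpnmb with 6 regions at 1.05 to 1.90, and Plin2, a lipid droplet coat gene, at 1.38. Of 24 resident macrophage regions at 13 genes, 18 fell and 6 rose (adjusted p = 0.000504 for the share that fell, 0.0106 with genes as units, where 11 of 13 were lower). The scavenger receptor gene Cd163 and the hyaluronan receptor gene Lyve1 were among those that fell, with log2 changes of -2.05 ± 0.328 and -1.82 at their largest. Regions of F13a1 and Folr2, and some of Klf4 and Maf, rose. Counted within 10 kb of gene starts, 90% of the resident regions were lower, but the list no longer passed (adjusted p = 0.0661, from a range of 1.24e-07 to 0.0661 over the alternatives). The main list tests did not match regions by their place relative to the gene, so a fall shared by gene starts is not set apart.

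Inflammatory genes moved in both directions. Of the 19 regions of the cytokine, chemokine and NF-kB list, 12 rose and 7 fell in HFD-RD against RD-RD, and the list did not differ from the other regions (Fisher's exact test, adjusted p = 1.0 in both directions). A region downstream of Tnfaip3, which encodes the NF-kB inhibitor A20, rose by 1.79 ± 0.293 (SE) and 1 downstream of Il12b, the interleukin 12 p40 gene, by 1.61 ± 0.305 (SE). The chemokine gene Ccl2 had a log2 change of -1.20 ± 0.215 (SE) at its region upstream of the gene (distance -24027 bp), and Ccl7, Cd86 and Nfkbiz also fell. Of 9 regions of Toll-like receptor signalling genes, which include Ikbkb, an NF-kB kinase gene, 8 rose, led by Tlr9, a sensor of unmethylated DNA, with 1.93 ± 0.205 (SE), and Tlr5, the flagellin receptor gene, with 1.25 ± 0.258 (SE), and 1 near Tlr3 fell (adjusted p = 0.619 for the share that rose).

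Angiogenesis genes were split too, with 17 of 31 regions higher and 14 lower (adjusted p = 0.76 and 0.523). All 5 regions of Angpt2, the angiopoietin 2 gene, rose, the largest by 2.60 ± 0.310 (SE), and the region upstream of Vegfa, the vascular growth factor gene, by 1.92 ± 0.234 (SE). Regions assigned to Efnb2, the ephrin B2 gene, fell, the largest with a log2 change of -2.54 ± 0.242 (SE) at a distance of 209134 bp, as did those of Vegfc and Mmp2. In the list of AP-1 and other signal-dependent factors, 15 of 17 regions rose, 1 fell and 1 did not pass (adjusted p = 0.267), with Batf and Bach2 both at 1.74. All 9 core macrophage regions, which lie at Irf8, Runx1 and Zeb2, rose (adjusted p = 0.241), the largest at Irf8 with 1.54 ± 0.220 (SE) and at Runx1 with 1.46 ± 0.271 (SE). The interferon list had a single region, upstream of Ifnar2, which rose by 1.21 ± 0.207 (SE). Of 6 glycolysis and oxidation regions 4 rose, led by Aldoa, the aldolase gene, at 1.68 ± 0.2 (SE), and 2 fell, Slc2a3, a glucose transporter gene, at -1.56 ± 0.416 (SE), and Pdk4 (adjusted p = 1.0).

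**Figure D1:**
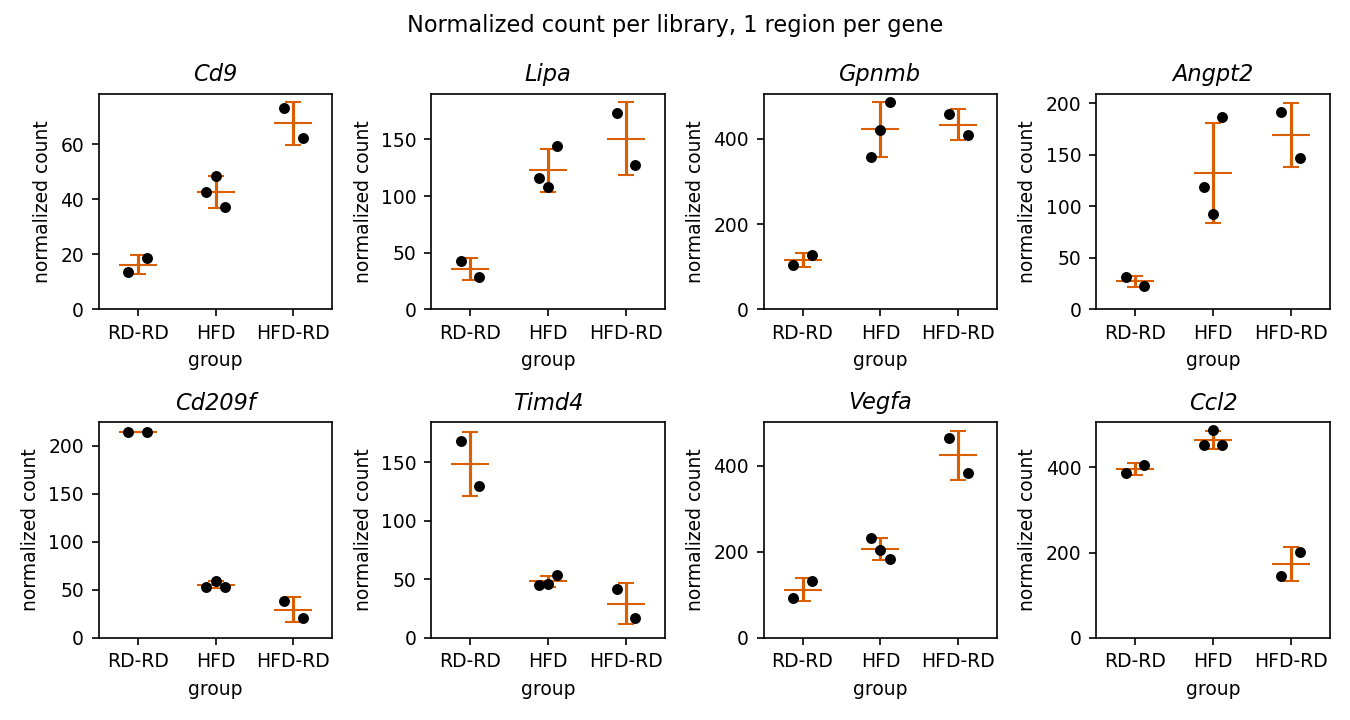
Normalized counts in 8 named regions, 1 per gene, by diet group; black points are libraries (n = 2 RD-RD, 3 HFD, 2 HFD-RD), orange dashes the group means and orange bars 1 SD. In Cd9 and Vegfa the HFD libraries lie between RD-RD and HFD-RD, and in Ccl2 HFD-RD lies below both other groups.

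Markers of other cell types that a macrophage sort can hold were few. No region was assigned to monocyte, NK cell, mast cell and eosinophil, or adipocyte markers. In HFD-RD against RD-RD, both neutrophil regions, 2 of 3 dendritic cell, 3 of 4 T cell, 4 of 5 B cell, 2 of 4 endothelial and 1 of 2 fibroblast regions fell, and each of the others rose. No marker list passed on its own (lowest adjusted p = 0.267, B cell). Cdh5, the VE-cadherin gene, had the largest change, -2.55 ± 0.227 (SE), at a region far upstream (distance -161342 bp), and Cd209a, a dendritic cell lectin gene, fell by 1.82 ± 0.192 (SE) at a region over its gene start. Taken as 1 list after the data were seen, 14 of the 20 marker regions fell (Fisher's exact test, adjusted p = 0.00674), but the list did not pass with genes as units (11 of 17 lower, adjusted p = 0.114), beside the resident macrophage regions that fell in the same comparison. In HFD against RD-RD 12 of the 20 fell (adjusted p = 0.0187; 0.138 with genes as units).

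The largest increases in HFD-RD against RD-RD were at regions assigned to Ap4e1 (3.24 ± 0.258, chromosome 2, 127035138 to 127035867), 1700020M21Rik (3.01), Adra1a (2.85), Fsd1l (2.81) and 5830417I10Rik (2.73), in log2 units with SE. The largest decreases were at 4933400L20Rik (-3.47 ± 0.234, chromosome 8, 103576960 to 103577734), Mir6414 (-3.41), Kctd16 (-3.33), Gm6313 (-3.31) and Gm8979 (-3.28). Adra1a encodes an adrenergic receptor, and its region lies upstream of the gene (distance -125921 bp). Coordinates follow GRCm38 and count from 1. No named region of this comparison lost its call under the alternatives that gave it a value; those of Fsd1l, 5830417I10Rik, Cd9, Batf and Slc2a3 had none with a minimum mean of 50.

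The comparison of HFD with RD-RD asks what the high-fat diet itself changes, though HFD mice were also 9 weeks shorter on study than RD-RD mice. The lipid-associated regions rose here as well. The region upstream of Gpnmb, a glycoprotein gene of lipid-laden macrophages, rose from 116 ± 15.6 normalized counts (SD, n = 2) to 423 ± 64.7 (SD, n = 3), a log2 change of 1.85 ± 0.202 (SE). A region inside Mitf, which encodes a regulator of lysosome genes, rose by 2.22 ± 0.253 (SE). Among resident macrophage genes, the start of Cd209f had a log2 change of -1.94 ± 0.244 (SE) and that of Timd4 one of -1.60 ± 0.313 (SE). Of all 314 gene-start regions, 75.8% fell in this comparison.

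Here limma called 3490 regions higher and 1710 lower in HFD, and 698 did not pass, with median log2 changes of 1.08 and -0.93 and a median SE of 0.211. The deposited tables read as holding this comparison have 2918 regions, 2205 higher and 713 lower by the authors' fold change. Of the 46 lipid-associated regions 45 rose and 1, inside Ctsd, did not pass at 0.39 ± 0.197 (SE) (Fisher's exact test, adjusted p = 2.13e-07; 0.00304 with genes as units). When only changes of at least 1 on the log2 scale counted as called, 56.52% of the list was higher and it no longer passed (adjusted p = 0.0959, range over the alternatives 6.43e-10 to 0.0959). Of the 24 resident regions 15 fell, 6 rose and 3 did not pass (adjusted p = 0.0128), but with genes as units the list did not pass (adjusted p = 0.334, range over the alternatives 3.54e-06 to 0.334).

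Of the 19 inflammatory regions 11 rose, 6 fell and 2 did not pass, with Il12b at 1.81 ± 0.278 (SE) and Tnfaip3 at 1.37 ± 0.214 (SE). This Tnfaip3 region is not the one given for HFD-RD against RD-RD, which rose by 0.86 ± 0.267 (SE) in HFD. Of the 9 Toll-like receptor signalling regions 6 rose, including Tlr9 at 1.64 ± 0.188 (SE) and Tlr1 at 1.07 ± 0.194 (SE), 1 fell and 2 did not pass. Of the 31 angiogenesis regions 17 rose, with Angpt2 at 2.20 ± 0.283 (SE) and Epas1, a hypoxia-inducible factor gene, at 1.95 ± 0.295 (SE), 12 fell and 2 did not pass. AP-1 and other signal-dependent factor genes had 13 regions that rose and 4 that did not pass, with Fos at 1.26 ± 0.202 (SE) and Egr2 at 1.15 ± 0.217 (SE). All 9 core macrophage regions rose, with Runx1 at 1.44 ± 0.247 (SE) and Irf8 at 1.40 ± 0.201 (SE), as did Ifnar2 at 0.97 ± 0.189 (SE). The Runx1 region given for HFD-RD against RD-RD is another, which rose by 0.84 ± 0.247 (SE) in HFD. The glycolysis list had 1 region that rose, Aldoa at 1.36 ± 0.183 (SE), and 5 that did not pass. None of these 7 lists differed from the other regions in the share that rose or fell (Fisher's exact test, lowest adjusted p = 0.0503, for the AP-1 list having 0 regions that fell).

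Of the markers of other cell types, both neutrophil regions, 2 of 3 dendritic cell regions, 2 of 4 T cell, 3 of 5 B cell, 2 of 4 endothelial and 1 of 2 fibroblast regions fell in HFD. Cdh5 had a log2 change of -1.53 ± 0.208 (SE) and Siglech, a gene of plasmacytoid dendritic cells, one of -1.46 ± 0.224 (SE) over its gene start. The largest increases were at Adra1a (2.95 ± 0.241), Kdm4b, a histone demethylase gene (2.89), Nron (2.77), Kcnk12 (2.75) and Apbb2 (2.71). The largest decreases were at Klhl13 (-2.54 ± 0.187, over the gene start on chromosome X), 1700123O21Rik (-2.28), F630206G17Rik (-2.22), 4933400L20Rik (-2.18) and Sema6a (-2.16).

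**Figure D2:**
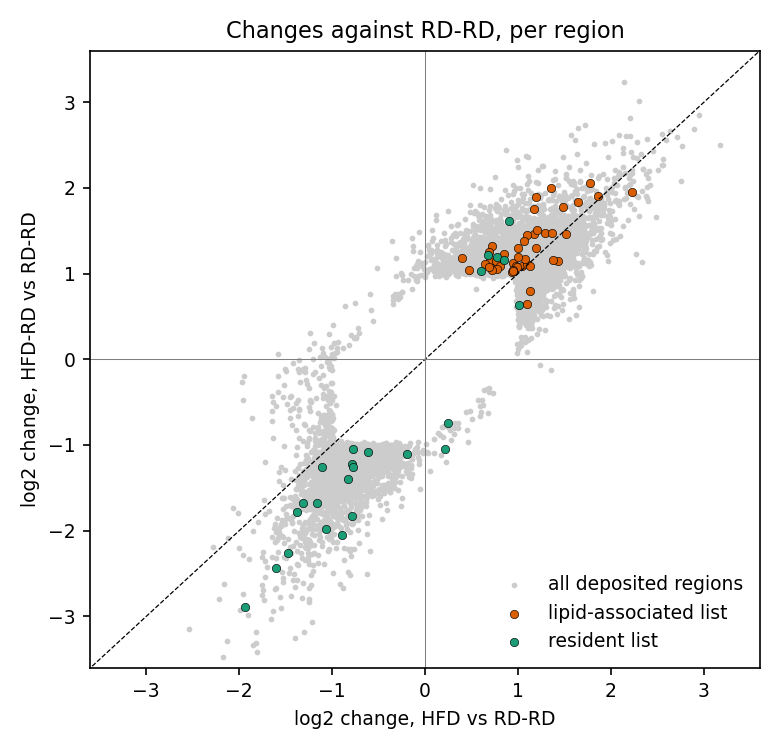
Log2 change of each of the 5898 deposited regions in HFD against RD-RD (horizontal) and HFD-RD against RD-RD (vertical), from limma; orange points are the 46 lipid-associated regions, green points the 24 resident macrophage regions, and the dashed line marks equal changes. The bands near 0 are sparse because of the authors' threshold of 1, but not empty, since a region had to pass it in only 1 comparison. The 46 orange points lie above 0 on both axes.

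The comparison of HFD-RD with HFD asks what differs between mice after weight loss and mice still on the high-fat diet, and it is confounded with time on study, 20 against 11 weeks. The region upstream of Vegfa rose by 1.03 ± 0.214 (SE), from 207 ± 25.4 normalized counts in HFD (SD, n = 3) to 424 ± 57.9 in HFD-RD (SD, n = 2), and the region upstream of Ccl2, which encodes the monocyte chemoattractant MCP-1, went from 464 ± 21 to 174 ± 39.5, a log2 change of -1.43 ± 0.196 (SE). The start of Lyve1, a marker gene of resident perivascular macrophages, had a log2 change of -1.04, in a comparison where 36.3% of all gene-start regions were lower. Of the 46 lipid-associated regions 3 were higher in HFD-RD, 0 were lower and 43 did not pass, which does not show that these are alike.

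Here limma called 603 regions higher and 757 lower in HFD-RD, while 4538 did not pass. The deposited tables read as holding this comparison have 403 regions, of which limma's log2 change was above 0 in 203 and below 0 in 200. The calls lean on single libraries: without HFD-RD replicate 1 they fell to 33 higher and 119 lower, without HFD replicate 1 to 223 and 271, without HFD replicate 2 to 400 and 503, and without HFD replicate 3 to 325 and 393. Among the libraries of HFD-RD and HFD, the drop was smallest without HFD-RD replicate 2. Each removal also leaves fewer libraries to test with, so part of the drops may not come from the library left out. The calls also lean on the scaling. Of them 44.3% were higher as reported and 18.5% with equal totals per library (361 higher, 1588 lower). With equal totals after setting aside the region with the most reads, 29% were higher. These rescalings moved the median of all regions by -0.209 and -0.113 here, by -0.191 and -0.235 in HFD-RD against RD-RD, and the latter also by -0.121 in HFD against RD-RD. Their totals count only the deposited regions, which were selected for differing between the groups. The largest region of a library held 14.27% and 9.948% of these reads in HFD-RD and 5.486% to 7.255% in HFD. Equal totals therefore carry such differences into the scaling.

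Of the 24 resident macrophage regions 9 were lower in HFD-RD than in HFD, 1 was higher and 14 did not pass (Fisher's exact test, adjusted p = 0.0225), but the list did not pass with genes as units (adjusted p = 0.162), and without HFD replicate 2 the share that fell dropped from 37.5% to 8.33% (adjusted p = 1.0). Without HFD replicate 1, HFD replicate 3 or HFD-RD replicate 2 the shares were 12.5%, 25% and 16.67%, and none passed, while without HFD-RD replicate 1 it was 20.83% and passed (range over the alternatives 0.000738 to 1.0). Of these regions Cd163 had a log2 change of -1.15 ± 0.3 (SE) and Igf1, which is also on the angiogenesis list, one of -1.26 ± 0.330 (SE). In the AP-1 list 7 of 17 regions rose, at Jun, Klf6, Bach1, Bach2 and Batf, 1 near Egr2 fell by 0.79 ± 0.217 (SE) and 9 did not pass (adjusted p = 0.0128). With genes as units the AP-1 list did not pass (adjusted p = 0.182), and without HFD-RD replicate 1 or without HFD replicate 1 none of its regions rose (0%). Without HFD replicate 2, HFD replicate 3 or HFD-RD replicate 2, 29.41% (adjusted p = 0.0529), 5.882% and 17.65% rose, and none passed (range over the alternatives 0.00138 to 1.0).

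In the lipid-associated list Ctsd, the cathepsin D gene, rose by 0.79 ± 0.197 (SE) and Cd9 by 0.65 ± 0.209 (SE), and its share that fell, 0%, was below that of the other regions (adjusted p = 0.032; 0.507 with genes as units; range over the alternatives 0.00033 to 1.0). Of 19 inflammatory regions 3 rose, among them Tnfaip3 at 0.93 ± 0.267 (SE), 2 fell and 14 did not pass. This is the Tnfaip3 region given for HFD-RD against RD-RD, and the one given for HFD against RD-RD did not pass at 0.05 ± 0.214 (SE). Of 9 Toll-like receptor signalling regions 2 rose, Tlr5 at 1.08 ± 0.235 (SE) and Ikbkb at 0.83 ± 0.252 (SE), and 7 did not pass. Of 31 angiogenesis regions 1 rose, Vegfa, 5 fell and 25 did not pass. Irf8 rose by 0.66 ± 0.187 (SE) at 1 of the 9 core regions, and 8 did not pass. Among these 8 was the Irf8 region given in the comparisons against RD-RD, at 0.14 ± 0.201 (SE). Pfkl, a glycolytic enzyme gene, rose by 0.83 ± 0.210 (SE), Pdk4, an inhibitor of pyruvate oxidation, had a log2 change of -0.88 ± 0.201 (SE), and 4 of the 6 metabolic regions did not pass. The interferon region at Ifnar2 did not pass. Among the markers of other cells Cdh5 fell by 1.02 ± 0.208 (SE), Cd209a fell, Xcr1, a dendritic cell receptor gene, rose by 0.90 ± 0.216 (SE), and the other 17 did not pass.

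The largest increases in HFD-RD against HFD were at 6820431F20Rik (1.75 ± 0.272), Vipr2 (1.74), Gm21379 on the Y chromosome (1.70), Dux (1.64) and Ccdc185 (1.58), and the largest decreases at Syt3 (-1.88 ± 0.280), Tesk1 (-1.87), P3h2 (-1.85), Pou2af1, a B cell coactivator gene (-1.85), and Nr2e3 (-1.78). For 15 of the named results of this comparison the call was lost under at least 1 alternative, 14 of them without HFD-RD replicate 1. These were Bach2, Ccdc185, Cd163, Cd9, Ctsd, Egr2, Igf1, Ikbkb, Irf8, Pdk4, Pfkl, Tlr5, Tnfaip3, Vegfa and Xcr1. Without that library the log2 change was 0.89 for Vegfa (adjusted p = 0.0862), 0.49 for Tnfaip3 (0.273) and 0.66 for Bach2 (0.252), by limma. Cd163 kept its call there and lost it without HFD-RD replicate 2, at -0.70 (adjusted p = 0.148).

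**Figure D3:**
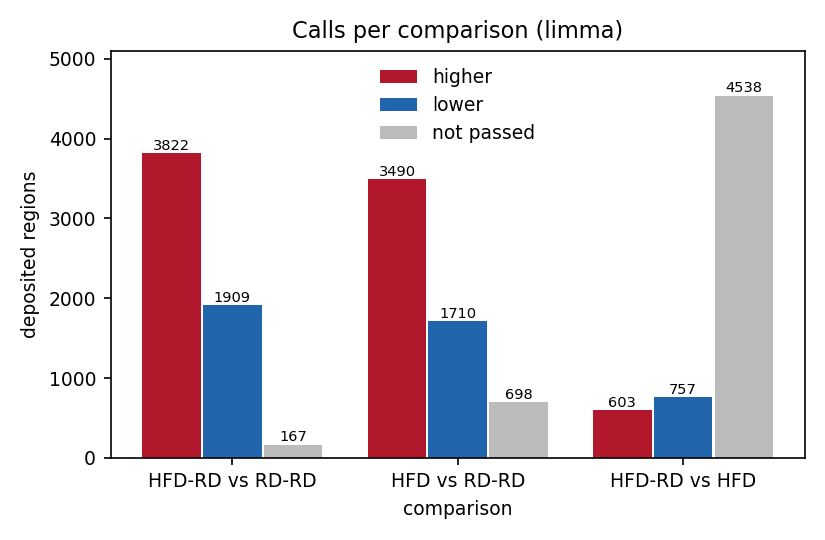
Deposited regions called higher (red), called lower (blue) and not passed (grey) in each comparison, from limma with Benjamini–Hochberg adjustment over the 5898 regions. Bars give counts, which run from 167 regions not passed in HFD-RD against RD-RD to 4538 in HFD-RD against HFD.

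The comparisons were also set against each other to ask whether HFD-RD macrophages lie on the same side of RD-RD as HFD macrophages. Of the 4989 deposited regions of HFD-RD against RD-RD, 4961 (99.44%, 95% interval 99.2 to 99.6, Clopper-Pearson) had a log2 change of the same sign in HFD, whether or not it passed there. Their median HFD change in that direction was 0.92, beside a median absolute change of 1.24 in HFD-RD, on which they were selected. For the 2918 deposited regions of HFD against RD-RD the medians were 1.21 in HFD and 1.23 in HFD-RD. The first medians therefore do not show weaker changes in HFD. The interval counts regions as units, though they are not independent and come from the same libraries. The 2084 regions in both sets include the named regions of Angpt2, Gpnmb and Lipa, which rose, and of Cd209f and Timd4, which fell. Of the 2905 regions called by the authors for HFD-RD and not for HFD, which include those of Vegfa, Ccl2 and Tlr5, 2877 (99.04%) had the same sign. Ccl2 was an exception, lower in HFD-RD and not shown to differ in HFD, where its log2 change was 0.23 ± 0.196 (SE). Many of the 2905 passed in HFD by limma. Of the 2689 called for HFD-RD against RD-RD alone, 1241 were higher in HFD than in RD-RD, 927 lower, and 521 did not pass. Of the 216 called for HFD-RD against both others, 31 were higher, 54 lower, and 131 did not pass. Both comparisons use the same RD-RD libraries, and in data simulated with no change in either group 68.4% of regions had the same sign, with a correlation across regions of 0.545, beside 98% and 0.907 for all deposited regions. The simulated regions were not selected by a threshold, as the deposited ones were. The simulated values are therefore not the chance values for the deposited regions.

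By set, 2689 regions were called by the authors for HFD-RD against RD-RD alone, 2022 for HFD-RD and HFD against RD-RD, 784 for HFD against RD-RD alone and 216 for HFD-RD against both others. A further 75 were called for HFD-RD against HFD alone, 62 in all 3 comparisons and 50 for HFD against both others. Of the 62, 52 were lower in HFD than in RD-RD, among them Cd209f and Cdh5, the only genes of a list there. By the sign of limma's change, the lists of higher regions against RD-RD shared 1545 regions, the lists of lower regions shared 539, and 0 regions were higher in one and lower in the other. Both lists rest on the same RD-RD libraries, and no overlap was computed for data with shared controls and no change.

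The regions over gene starts behaved unlike the rest. Of the 314 regions that overlap the start of their assigned gene, 283 (90.1%, 95% interval 86.3 to 93.2) fell in HFD-RD against RD-RD and 25 rose, with a median log2 change of -1.20 (SD 0.772 over regions). They made up 14.8% of the 1906 annotated regions that fell and 0.778% of the others (Fisher's exact test, two-sided, adjusted p = 6.12e-106 over 65 annotation tests). The annotation tests and the interval count regions as units, though regions are not independent. They do not measure the spread between mice. In HFD against RD-RD 238 fell (75.8%, adjusted p = 5.15e-69), and in HFD-RD against HFD 114 fell and 4 rose (adjusted p = 6.33e-27). With promoters taken as within 5 kb of the gene start, the lack of these regions among the higher ones in HFD-RD against HFD was gone (16.6%, adjusted p = 0.557).

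The gene-start regions named next were chosen after their values were seen. The largest decreases in HFD-RD against RD-RD were at the starts of Klhl13 (-3.15 ± 0.204, SE), Cd209f, Prima1 (-2.83), Cd209d (-2.78) and Sema6a (-2.74), a semaphorin gene. Gene starts that rose included those of Angpt2 (1.33 ± 0.327, SE) and Atp6v0d2 (1.30 ± 0.228, SE), a subunit gene of the lysosomal proton pump. Regions inside genes were more common among those that rose in HFD-RD (39.1%) than among the others (28.6%, adjusted p = 3.52e-15). The median distance from a region to the start of its assigned gene was 28030 bp, and 16.2% of regions lay over 100 kb away, so the assignment to a gene is by nearness only.

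**Figure D4:**
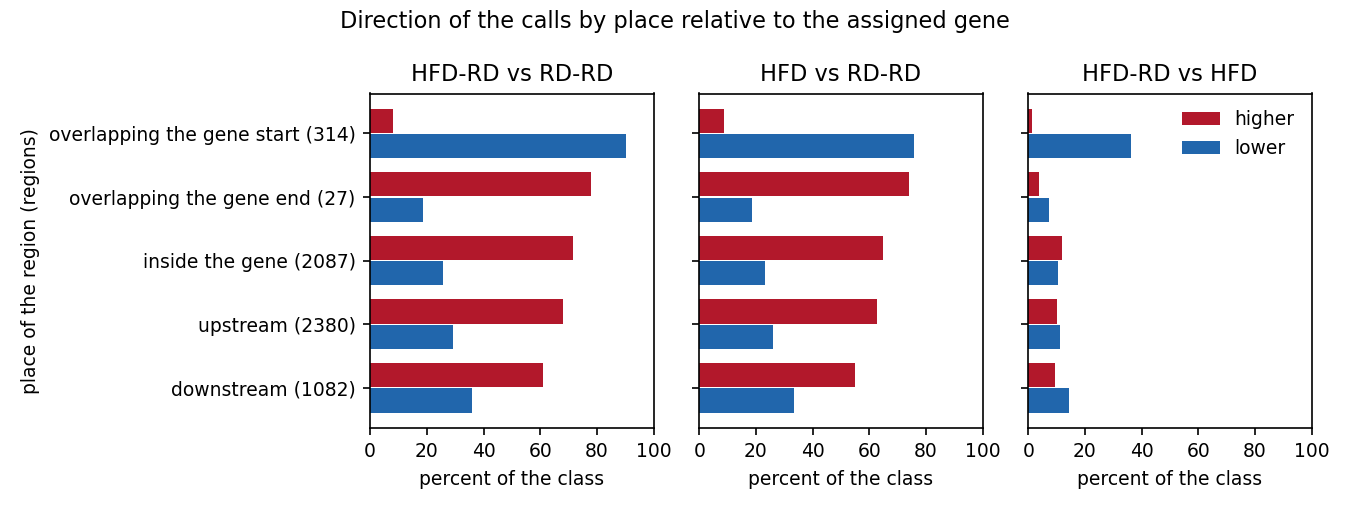
Percent of the regions of each place relative to the assigned gene that were called higher (red) or lower (blue) in each comparison by limma, with the number of regions in brackets. Of the 314 regions over gene starts 90.1% were lower in HFD-RD than in RD-RD, against 25.6% of the 2087 regions inside genes.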

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

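The rescaling to equal totals, the nearest coding gene body and the lists counting only log2 changes of at least 1 were chosen after seeing the data. The numbers of calls against RD-RD moved by less than 1.5 times when each library was left out, with 3534 to 3821 higher regions for HFD-RD and 2999 to 3509 for HFD, which does not say that the same regions were called. Of 83 named results 15, all in HFD-RD against HFD, lost the threshold somewhere and 0 reversed; 75 of them had a value with a minimum mean of 50. With a log2 change of at least 1, HFD against RD-RD had 2177 higher and 707 lower regions, and with 1 region per gene 2186 higher, beside 2374 for HFD-RD; fewer units were counted. The calls of HFD-RD against HFD moved most: 118 higher and 158 lower at an adjusted p under 0.01, 191 and 209 at a log2 change of at least 1, 361 and 1588 with equal totals, 1172 lower with equal totals without the top region, and 33 to 724 higher and 119 to 856 lower without 1 library. With the replicate block they were 180 higher and 241 lower, but the replicate numbers do not pair the libraries (correlations of -0.0716 to 0.0628 between same-numbered ones). Only HFD has a replicate 3, so the block takes that library out of the estimate. The log2 change of Cd9 was 0.5572 both with the block and without HFD replicate 3. The block is therefore not a check apart from that removal. The share with the same sign was 98.44% to 99.5% without 1 library for regions called for HFD-RD, 98.22% to 99.79% for those called for HFD and 97.31% to 99.14% for those called for HFD-RD and not HFD. With equal totals without the top region it was 98.94% and 98.18% for the first and last, and 100% for all 3 with a log2 change of at least 1 in both, which that selection nearly fixes.

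Regions over gene starts were 10.7% of the 75 regions deposited for HFD-RD against HFD alone, taken within 1 kb (adjusted p = 0.0872), and 16.6% of the regions limma called higher in HFD-RD against HFD, taken within 5 kb. Resident macrophage regions within 10 kb were 10% higher and 90% lower in HFD-RD against RD-RD, 10% and 80% in HFD against RD-RD, and 50% lower in HFD-RD against HFD. Of all 24 resident macrophage regions, at any distance, 25% were higher in HFD against RD-RD without each HFD library in turn. Without RD-RD replicate 1, which left a lone library in that group, the call was lost. With genes as units they were 23.08% higher and 61.54% lower in HFD against RD-RD and 46.15% lower in HFD-RD against HFD. Counting log2 changes of at least 1, they were 33.33% lower in HFD and 12.5% lower in HFD-RD against HFD, the lipid-associated regions were 56.52% higher and 0% lower in HFD, and 5.882% of AP-1 regions were higher in HFD-RD against HFD. In that comparison the resident share lower was 54.17% with equal totals and 8.333% to 37.5% without 1 library. The lipid-associated share lower stayed at 0%, without its call, within 10 and 100 kb, with genes as units, with the replicate block and without 5 of the libraries in turn, and was 1.887% by coding gene body. The AP-1 share higher was 100% within 10 kb, but this rested on a lone region, near Bach1 (distance -8525 bp), and the list did not pass. The AP-1 share higher was 40% within 100 kb, 50% with genes as units, and 17.65% by coding gene body and with equal totals. It was 0% with the replicate block, and 0% to 47.06% without 1 library. Except where fewer units or libraries were counted, the cause was not tested. Leaving out 1 library of a group of 2 left a lone library that is assumed to vary like the others. The filter of 10 removed 0 regions, so its absence tested nothing. Not run were count-based tests, planned only for tables of raw counts, for which voom on the recovered reads stood in, motif searches, since no genome was used, and the nearest gene start, since the gene table has no strand.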

Other observations

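The tests of the first and second of the 3 patterns weighed in this part were chosen only after the results were seen, as were the genes of the next paragraph; the tests of gene-start regions were written before their results, after the pattern itself was noticed. In the first pattern the set of regions and both tests, and in the second the multi-copy, whole-Y and depth tests, were changed after a first run. Tests of a further pattern, the rise of lipid-associated regions, were run and left out for length.

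Some genes gathered many of the deposited regions, nearly all moving together. All 12 regions of Lhfpl2, all 10 of Camk2d, a calcium/calmodulin-dependent kinase gene, all 10 of Xylt1, which encodes a xylosyltransferase of proteoglycan synthesis, and all 10 of Abhd17c, a depalmitoylase gene, rose in HFD-RD against RD-RD, with median log2 changes of 1.31, 1.17, 1.14 and 1.70. In HFD against RD-RD 10, 9, 8 and 10 of them rose. H2afy3 had 13 regions, of which 12 rose in HFD-RD and 11 in HFD. All 10 regions of Celf4, an RNA-binding protein gene, fell in both comparisons, with medians of -1.60 in HFD-RD and -0.97 in HFD, and 4 fell further in HFD-RD against HFD. Of the 10 regions of Adgrl2, 7 rose and 3 fell in HFD-RD, and the most distant lay 788612 bp away.

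The first pattern is that regions the authors called for HFD-RD against RD-RD lay on the same side of RD-RD in HFD by sign, 4961 of 4989. For the 2093 of these regions that moved by over 1 in HFD in the same direction, chance values of the shared RD-RD libraries are argued against only if all tested regions vary alike. From the 5 deposited regions with such an error of the RD-RD mean, 63 of the 74287 tested would then have it (upper bound 147). Selection for a difference favours regions whose libraries agree, so these expected numbers may be too low. For the regions with smaller changes sharing may account for the sign, and this stays open. In data simulated with the observed HFD-RD changes and none in HFD, 56.9% of regions over 1 in HFD-RD had the same sign. Their median HFD change was 0.036, beside 99.04% and 0.714 for the 2905 regions not called for HFD. That simulation takes the observed HFD-RD changes as true and leaves out the chance part of the authors' selection, so it does not decide. The regions not called for HFD could differ from the others only by where the authors' thresholds fall, and this stays open: limma called 947 of 2905 (32.6%, 30.9 to 34.3) different between HFD-RD and HFD, all farther from RD-RD in HFD-RD as their selection favours, against 0.907% in data simulated with equal effects, while 1958 were not shown to differ. A chromatin state kept after weight loss is a candidate explanation that the design names, but time on study and the mix of macrophage types in the sort were not tested.

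The second pattern is a set of 13 regions, 7 on the Y chromosome (6 near Zfy1 and 1 near Gm21379) and 6 on unplaced or unlocalized contigs, that were lower in HFD than in both other groups, with a median log2 change of -1.20 (SD 0.284) against RD-RD; 19 deposited regions lie off the autosomes and X. Lower coverage of the whole Y chromosome stays open: at the other 2 deposited Y regions, near Sly and Usp9y, HFD-RD exceeded HFD by at most 0.883 with 2 SE added, below the pattern's median of 1.22, but these are the Y regions that the pattern's own selection left out. A shared multi-copy source that varies between libraries could be the cause, since the regions differed by a median of 0.851 (SD 0.177) between the HFD-RD libraries, near the edge of the central range of other regions (-0.715 to 0.888), which does not decide it. Deeper sequencing of HFD also stays open: across the HFD libraries the mean log2 level was 7.845, 7.911 and 7.748 at size factors of 2.21, 1.22 and 1.16, with no fall at the highest, while in HFD-RD it was 9.522 at 0.548 and 8.659 at 1.08. In RD-RD the level was 9.164 at 0.803 and 9.081 at 0.694, with no fall at the higher size factor. The slope within groups, -0.384 (-1.26 to 0.493), was not shown to differ from the -1.36 between HFD-RD and HFD (difference -0.972, -2.21 to 0.269). No biological explanation was tested.

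The third pattern is the fall of gene-start regions. Less background in the RD-RD libraries is argued against only in a form that affects strong regions wherever they lie. At most 24.8% (23.5 to 26.1) of regions away from gene starts, weighted to the same mean counts, fell, against 90.1%. These regions were themselves selected for a difference and were matched on mean count alone. A difference in background that acts on gene starts in particular is not covered by this comparison. The authors' size factors stay open for the fall itself: 73.9% (68.7 to 78.7) or more of the gene-start regions fell under both rescalings, but these moved the median of all regions by -0.235 to 0.0175, so the falls could not be lost and the test, though written first, decides nothing. Library quality that varies within a diet group stays open. Relative to the other regions, gene-start regions differed by at most 0.187 between libraries of the same group, against 1.57 between HFD and RD-RD. The regions were selected for differing between these groups, which favours agreement within a group, so this does not decide it. The 1.57 also counts the rise of the other regions, since the gene-start regions themselves had a median log2 change of -0.76 in HFD. A lower accessibility of these promoters in mice that ate the high-fat diet may be the cause, but sequence composition, the mix of cell types and a difference in quality that follows the diet groups were not tested.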
